A study of Mus musculus with 15 samples.

How the data were processed

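Livers of 15 C57BL/6 mice were sampled after 3 days of a ketogenic diet, a high-fat diet or chow, 5 per diet, and total RNA was extracted with Trizol, per the labels' protocols. Label numbers run in blocks by diet and none recurs (1, 5, 7 and 13 are absent, with no reason given). Each library was taken as 1 mouse, unpaired. Batch, date, sex, food intake and the age of the chow mice are not given in the sources used here. Any batch that followed the diets has the same contrast.

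Trimmomatic 0.36, which trims reads, kallisto 0.44, which assigns them to transcripts, edgeR 3.28 and build GRCm38.p6 are named in the submitters' processing notes, with no settings. The deposited tables hold 1 line per transcript (106332 transcripts) with an estimated count, the number of reads kallisto assigned, which is often fractional where transcripts share reads. They also hold TPM, per the file headers, which is that count scaled by effective length and depth. TPM served only to weight transcripts when the effective length and GC content of each gene were averaged. Whole numbers made up 9.2 to 10.6% of the estimated counts above 0, with no tolerance. In 9503 of 11494 transcripts with at least 100 reads in every library, the effective length exceeded the transcript length in some library. How those lengths were made is not given in the sources used here.

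Estimated counts were summed per gene with the GENCODE M21 annotation, which matched 105734 transcripts to 25731 genes, and rounded to whole numbers. The other 598 transcripts, with 0.184 to 0.223% of the reads, were left out of library sizes and tests. The annotation release used by the submitters is not given, and M21 was taken for its match to the transcript identifiers. Genes were kept by edgeR's filterByExpr (minimum count 10, total 15), which left 13967. edgeR 4.0.16 fitted all 15 libraries together with TMM factors and robust quasi-likelihood dispersion (residual degrees of freedom 12), since the 3 diets then share 1 estimate of the spread. Each pair of diets was tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. These adjusted p values apply wherever a gene's adjusted p is given. Normalised CPM used the TMM library sizes. Principal components used log2 CPM (prior count 2) of the 1000 most variable genes. Other software was R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

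The 49 gene lists, the tests of genes and lists and all alternatives but total-count scaling were fixed before the data were examined. Tests of short transcripts, Mup paralogs and female livers, and the division of sex-biased genes by direction, were chosen after results were seen. The lists cover fatty acid oxidation, PPARalpha targets, ketogenesis, lipid droplets, fatty acid and triglyceride synthesis, cholesterol, lipoproteins, bile acids, gluconeogenesis, glycolysis with fructose and glycogen, insulin signalling with FoxO1 targets, the tricarboxylic acid cycle, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, amino acid catabolism, the urea cycle, one-carbon metabolism and xenobiotic metabolism. They also cover growth hormone and sex-biased genes, the acute phase, interferon, inflammation, MHC class II, extracellular matrix, the unfolded protein and integrated stress responses, NRF2, heat shock, lysosome and autophagy, the clock, the cell cycle, immediate early genes, ribosomal proteins and markers of liver and other cell types. Lists with at least 3 members tested (48) were tested with camera (limma, preset correlation 0.01), with Benjamini-Hochberg adjustment over lists in each comparison, and again with an estimated correlation and with fry. Members were also adjusted over the list alone.

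Genes were named by a rule fixed beforehand. It takes the 6 largest rises and 6 largest falls per comparison with adjusted p under 0.05, a mean of at least 5 CPM in the higher diet and no overlap between the diets' libraries, leaving out predicted, mitochondrially encoded and pseudogenes. It adds up to 4 members of each list with the smallest adjusted p, and a panel of 25 genes, of which 21 are reported here. Where a count of 5 or fewer is given, its genes are named outside the rule and were chosen after their values were seen, as were the genes listed as called in both comparisons with chow. Genes from families of near-identical copies (Mup, Cyp2a, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Gstm, Serpina, Saa, Acot) are uncertain one by one, since shared reads could be split between copies.

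Between replicates the chi-square per degree of freedom was 18.35 to 110.47 over 30 pairs, and the common biological coefficient of variation was 0.1306, so that variation between mice, more than read number, limited precision. The code was tested on simulated data with 13762 genes. For ketogenic against chow it recovered 79.1, 97 and 100% of changes of 1.5, 2 and 4 times, with 8 false calls among 192, and it made 0 calls in a comparison with no change.

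Alternatives were DESeq2, limma-voom, RLE factors, no low-count filter, a stricter filter (CPM over 1 in 5 libraries), only the 2 diets compared, offsets for effective length and for GC content (loess span 0.5), protein-coding genes only and leaving out each library. Scaling by total count alone was added after seeing the data. For the comparison of the diets' responses, 20 simulations of unchanged diets and a split of the chow libraries into parts of 2 and 3 were run.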

Results

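RNA sequencing of total RNA was performed on 15 mouse livers of the C57BL/6 genotype, an inbred laboratory strain. Mice received a ketogenic diet, which is very low in carbohydrate, a high-fat diet or chow for 3 days, with 5 libraries per diet. The ketogenic and high-fat diets were given at 12 weeks of age. The age of the chow mice, the composition of the diets, the sex of the mice and their food intake are not given in the sources used here. Summed estimated read counts ran from 34707597 to 50914494 in the ketogenic libraries, from 30121672 to 44764257 in the high-fat libraries and from 30190806 to 43688344 in the chow libraries. Between 13322 and 14126 genes per library had at least 10 reads, and 13967 genes were tested. Major urinary proteins, small pheromone carriers secreted by the liver, took 4.62 ± 0.92% of the reads on the ketogenic diet, 11.2 ± 3.11% on the high-fat diet and 10.2 ± 2.57% on chow (SD, n = 5). Albumin (Alb), the main plasma protein, took 6.91 ± 0.24%, 5.29 ± 0.0799% and 6.28 ± 0.554%, and mitochondrially encoded genes took 9.81 ± 0.351%, 11.8 ± 0.751% and 12.0 ± 0.26%, in the same order. The first principal component of the 1000 most variable genes held 37.79% of their variance and set the ketogenic libraries (scores 17.72 to 28.35) apart from all others (-22.15 to -4.08). Along the second, with 12.65%, chow libraries scored 7.56 to 15.64 and high-fat libraries -16.04 to -9.26.

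**Figure D1:**
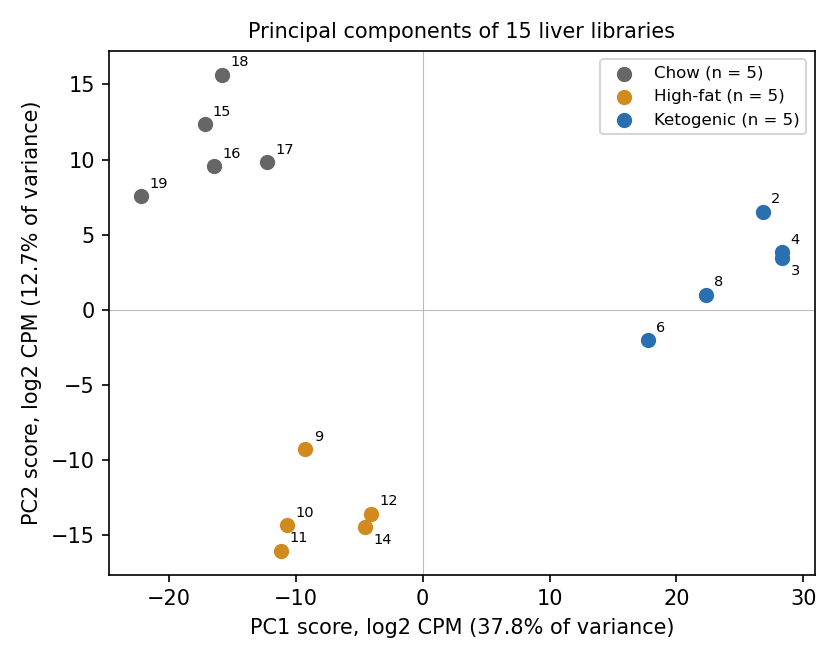
Scores of the 15 libraries on the first (37.79% of variance, horizontal) and second (12.65%, vertical) principal components of log2 CPM of the 1000 most variable genes, with scores in log2 CPM, 1 point per library, coloured by diet and numbered by replicate. The 5 ketogenic libraries all score 17.72 or more on the first component, and the other libraries -4.08 or less.

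Positions are given on build GRCm38 as annotated in GENCODE M21. Cpt1a (ENSMUSG00000024900.5) lies on chromosome 19 from 3322334 to 3385733. Bdh1 (ENSMUSG00000046598.15) lies on chromosome 16 from 31422280 to 31458901. Fgf21 (ENSMUSG00000030827.5) lies on chromosome 7 from 45613886 to 45615490. Cidec (ENSMUSG00000030278.11) lies on chromosome 6 from 113424634 to 113435760. Scd1 (ENSMUSG00000037071.3) lies on chromosome 19 from 44394455 to 44407879. Fasn (ENSMUSG00000025153.9) lies on chromosome 11 from 120805846 to 120824547. Nnmt (ENSMUSG00000032271.13) lies on chromosome 9 from 48591877 to 48605153. Csad (ENSMUSG00000023044.2) lies on chromosome 15 from 102176999 to 102204724. Cyp3a11 (ENSMUSG00000056035.8) lies on chromosome 5 from 145854426 to 145879964. Each of these is annotated as a protein-coding gene, and the values are sums over its transcripts.

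The study asks how a ketogenic diet acts on insulin resistance, fat storage and scarring in the liver, and the comparison with chow measured what 3 days of that diet changed in liver transcripts. Of 36 genes for burning fatty acids 33 rose, and of 10 for making and moving ketone bodies 9 rose. Of 30 genes for making fat 18 fell and 4 rose. That list call was lost with an estimated correlation (adjusted p = 0.308), not with fry (0.00111). Cpt1a, which admits long-chain fatty acids to mitochondria, rose 3.46-fold, from 181 ± 15.8 to 626 ± 52.9 normalised CPM (SD, n = 5 per diet). Bdh1, which forms the main circulating ketone body, rose 2.76-fold, from 131 ± 6.39 to 361 ± 50.6. Scd1, which desaturates newly made fatty acids, fell 99.4-fold, from 11987 ± 4402 to 121 ± 55.9, and Fasn, the fatty acid synthase, fell 3.29-fold, from 546 ± 281 to 166 ± 39.3. Adjusted p (edgeR quasi-likelihood test, Benjamini-Hochberg) was 6.52e-10 for Cpt1a, 2.13e-09 for Bdh1, 3.43e-07 for Scd1 and 6.68e-04 for Fasn, and the 5 values of each diet did not overlap for any of these. In all, 2258 genes rose and 2038 fell, together 30.8% of the 13967 tested, of which 258 rose and 271 fell at least 2-fold. With scaling by total count only, an alternative chosen after seeing the data, rises made up 68.5% of the calls against 52.6%, and 1265 genes fell.

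Among genes whose ketogenic and chow libraries did not overlap, Cidec, a lipid droplet protein that enlarges fat stores, rose by 4.47 ± 0.40 on the log2 scale (SE; adjusted p = 3.92e-06) from 1.60 ± 0.781 to 35.4 ± 9.47 CPM. Apoa4, an apolipoprotein of triglyceride-rich particles, rose by 3.76 ± 0.38 (adjusted p = 9.78e-06) from 137 ± 44.0 to 1853 ± 1058 CPM. The metal-binding Mt2 and the iron-siderophore binder Lcn2 rose by 5.23 ± 0.92 and 4.23 ± 0.65, with adjusted p = 9.13e-04 and 3.38e-04. Mt2 rose by 4.46 without ketogenic replicate 4. Cyp2b9 and Cyp2a22, cytochrome P450 genes, rose by 7.06 ± 0.86 and 4.21 ± 0.35 (adjusted p = 5.93e-05 and 1.37e-06), and Cyp2b9 by 7.66 without chow replicate 18. Their values per gene are uncertain, since near-identical copies share reads. Besides Scd1 (log2 fold change -6.64 ± 0.46), large falls were in Chrna4, a nicotinic receptor subunit (-5.77 ± 0.72, adjusted p = 7.22e-05), and Adgrf1, an adhesion receptor (-4.08 ± 0.36, adjusted p = 1.17e-06). Mup2, Cyp2c40 and Mup7, each from a family of near-identical copies and so uncertain per gene, had log2 fold changes of -3.89 ± 0.64, -3.70 ± 0.60 and -3.60 ± 0.57, and Mup2 of -4.65 without ketogenic replicate 6.

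In the fixed panel, the hormone gene Fgf21 rose by 3.04 ± 0.55 (adjusted p = 0.00105) and the fatty acid hydroxylase Cyp4a14, which has close paralogs, by 2.13 ± 0.39 (adjusted p = 0.00109). Angptl4, a lipase inhibitor, rose by 1.01 ± 0.29 (adjusted p = 0.0186). Pck1, a gluconeogenic enzyme, rose by 1.29 ± 0.40 (adjusted p = 0.0275, between 0.00475 and 0.0649 over 20 alternatives), a call lost without ketogenic replicate 4 or 6 or chow replicate 15, 18 or 19 (adjusted p = 0.0649, 0.0524, 0.0594, 0.0584 and 0.0508). Srebf1, the regulator of fat synthesis genes, and Pklr, liver pyruvate kinase, had log2 fold changes of -1.02 ± 0.19 and -1.48 ± 0.16 (adjusted p = 8.27e-04 and 7.46e-06). Saa1, an acute phase protein, did not pass (log2 fold change 1.75 ± 0.63, adjusted p = 0.0541, between 0.0128 and 0.210 over 20 alternatives), and passed with all libraries under DESeq2 (adjusted p = 0.0128), the stricter filter (0.0496) and total-count scaling (0.0460), and without ketogenic replicate 2 or 8 (0.0353 and 0.0325). Without ketogenic replicate 4 it had a log2 fold change of 0.84, and Igfbp1, also not passed, one of 0.22 against 0.93 ± 0.67. Genes of glucose handling (G6pc, Pdk4, Igfbp1, Irs2), bile acid synthesis (Cyp7a1), macrophages (Adgre1), chemokines (Ccl2) and scar collagen (Col1a1) did not pass, with log2 fold changes between -0.30 and 0.93. The cytokine genes Il6 and Tnf and the protease inhibitor gene Timp1 had between 0 and 9 reads in each library and were not tested in any comparison. Timp1 had 31 reads in all on the ketogenic diet, 14 on the high-fat diet and 4 on chow.

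In the gene lists fixed beforehand, values in brackets after ± are SE, and camera compares a list with all other genes. Of the 36 genes of fatty acid oxidation in mitochondria and peroxisomes, 33 rose and 3 did not pass (33 rose adjusted over the list alone). Acadl, Acadm and Hadhb, enzymes of the oxidation spiral, rose (log2 fold changes 1.07 ± 0.061, 1.28 ± 0.075 and 1.14 ± 0.075), with a list median of 0.75, camera adjusted p = 6.26e-46, adjusted p = 0.0185 with an estimated correlation. Among the 32 targets of the fatty acid sensor PPARalpha, 25 rose, 1 fell (Pltp) and 6 did not pass (26 rose and 1 fell adjusted over the list alone). Fabp2 and Mgll, a fatty acid carrier and a lipase, rose (log2 fold changes 1.87 ± 0.097 and 1.25 ± 0.10), beside a list median of 1.16, camera adjusted p = 1.49e-25, adjusted p = 0.0253 with an estimated correlation. Of the 10 genes of ketone body synthesis and transport, 9 rose, 1 fell (Acss2), with none short of the threshold (9 rose and 1 fell adjusted over the list alone). Bdh1 and Slc16a7, which interconvert and move ketone bodies, rose (log2 fold changes 1.46 ± 0.087 and 1.38 ± 0.089), and the list as a whole had a median of 0.95, camera adjusted p = 1.80e-15, adjusted p = 0.00363 with an estimated correlation. From the 23 genes of lipid droplets and lipolysis, 15 rose, 3 fell (Pnpla3, Abhd5, Lpl) and 5 did not pass (16 rose and 3 fell adjusted over the list alone). Plin5, a droplet coat protein, rose (log2 fold change 1.32 ± 0.098) and Pnpla3 fell (log2 fold change -5.57 ± 0.38), with a list median of 0.88, camera adjusted p = 1.29e-10, adjusted p = 0.0127 with an estimated correlation.

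Of the 30 genes of fatty acid and triglyceride synthesis, 4 rose (Acsl1, Mogat1, Fads2, Fads1), 18 fell and 8 did not pass (4 rose and 18 fell adjusted over the list alone). Me1 and Mlxipl, a source of NADPH and a glucose sensor, fell (log2 fold changes -2.18 ± 0.17 and -1.22 ± 0.11), beside a list median of -0.50, camera adjusted p = 2.72e-07, adjusted p = 0.308 with an estimated correlation. Of the 23 genes of the tricarboxylic acid cycle, which oxidises acetyl groups, 14 rose, 3 fell (Dlat, Pdhb, Cs) and 6 did not pass (14 rose and 3 fell adjusted over the list alone). Suclg2, Suclg1 and Pdha1 rose (log2 fold changes 0.57 ± 0.062, 0.60 ± 0.068 and 0.42 ± 0.051), and the list as a whole had a median of 0.26, camera adjusted p = 7.05e-06, adjusted p = 0.400 with an estimated correlation. Among the 20 genes of glucose synthesis, 9 rose and 11 did not pass (10 rose adjusted over the list alone). Gk, Pcx and Gpt, which feed glycerol, pyruvate and alanine into it, rose (log2 fold changes 1.28 ± 0.083, 0.85 ± 0.095 and 0.55 ± 0.10), with a list median of 0.29, camera adjusted p = 2.35e-04, adjusted p = 0.250 with an estimated correlation. Of the 29 genes of insulin signalling and FoxO1 targets, 11 rose, 1 fell (Ppp1r3b) and 17 did not pass (11 rose and 2 fell adjusted over the list alone). Igfbp2, Trib3 and Pdpk1, an IGF carrier, an AKT inhibitor and a kinase, rose (log2 fold changes 0.93 ± 0.15, 1.16 ± 0.21 and 0.36 ± 0.071), beside a list median of 0.19, camera adjusted p = 0.0473, adjusted p = 0.498 with an estimated correlation. Leaving out ketogenic replicate 4, 6 or 8 or chow replicate 15 or 19 ended the list call (adjusted p between 0.0556 and 0.0901). Of the 42 genes of amino acid breakdown, 23 rose, 8 fell and 11 did not pass (25 rose and 8 fell adjusted over the list alone). Agxt2 and Mut, of glyoxylate and propionate handling, rose (log2 fold changes 0.90 ± 0.076 and 0.52 ± 0.058) and Cbs and Haao fell (log2 fold changes -0.71 ± 0.075 and -0.59 ± 0.072), and the list as a whole had a median of 0.30, camera adjusted p = 1.53e-04, adjusted p = 0.558 with an estimated correlation. From the 21 genes of methyl group metabolism, 11 rose, 2 fell (Cbs, Mthfd2) and 8 did not pass (11 rose and 3 fell adjusted over the list alone). Mat1a, which makes the methyl donor, rose (log2 fold change 1.06 ± 0.12), with a list median of 0.35, camera adjusted p = 0.0204, adjusted p = 0.558 with an estimated correlation. Without chow replicate 19 the list call was lost (adjusted p = 0.0563).

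Of the 44 genes of the proteins of the cytosolic ribosome, 31 fell and 13 did not pass (41 fell adjusted over the list alone). Rpl37 and Rps23 fell (log2 fold changes -0.43 ± 0.065 and -0.38 ± 0.069), beside a list median of -0.27, camera adjusted p = 4.10e-09, adjusted p = 0.558 with an estimated correlation. Among the 31 genes of the antioxidant response driven by NRF2, 2 rose (Gpx1, Sod2), 14 fell and 15 did not pass (2 rose and 14 fell adjusted over the list alone). Ephx1 and Ugdh, of epoxide and glucuronide chemistry, fell (log2 fold changes -0.98 ± 0.11 and -0.77 ± 0.088), and the list as a whole had a median of -0.26, camera adjusted p = 4.81e-07, adjusted p = 0.183 with an estimated correlation. Of the 31 acute phase genes, which encode plasma proteins of injury, 18 rose, 4 fell (Serpina3k, Fgg, Orm1, Fgb) and 9 did not pass (19 rose and 4 fell adjusted over the list alone). Saa4 and Steap4, a serum amyloid and a metalloreductase, rose (log2 fold changes 1.37 ± 0.14 and 1.03 ± 0.12), with a list median of 0.59, camera adjusted p = 7.45e-07, adjusted p = 0.250 with an estimated correlation. Of the 33 genes that handle foreign compounds, 18 rose, 4 fell (Cyp1a1, Ugt2b5, Cyp2c29, Cyp1a2) and 11 did not pass (18 rose and 6 fell adjusted over the list alone). Cyp2e1, Por and Fmo5, oxidases and their electron donor, rose by 1.06 ± 0.089, 1.34 ± 0.15 and 0.87 ± 0.11. The list median was 0.60, camera adjusted p = 6.20e-05, 0.039 without ketogenic replicate 8 and 0.319 with an estimated correlation. From the 19 heat shock genes, 8 rose and 11 did not pass (10 rose adjusted over the list alone). Hspb8, Dnaja1 and Hspa8, which are chaperones, rose (log2 fold changes 0.72 ± 0.057, 0.96 ± 0.091 and 1.22 ± 0.13), and the list as a whole had a median of 0.33, camera adjusted p = 2.90e-04, adjusted p = 0.503 with an estimated correlation. Of the 19 clock genes, 8 rose, 2 fell (Arntl, Npas2) and 9 did not pass (8 rose and 2 fell adjusted over the list alone). Hlf, Tef and Nr1d2, which time daily transcription, rose (log2 fold changes 0.68 ± 0.083, 0.71 ± 0.100 and 1.21 ± 0.15), with a list median of 0.19, camera adjusted p = 0.0167, adjusted p = 0.183 with an estimated correlation. Fgb lost its call without ketogenic replicate 2, 3, 4 or 8 or chow replicate 16, 17 or 19 (adjusted p between 0.0597 and 0.119).

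Of the 33 liver genes under growth hormone or with a sex bias, 6 rose, 16 fell and 11 did not pass (6 rose and 17 fell adjusted over the list alone). Cyp17a1, a steroid hydroxylase, rose (log2 fold change 2.03 ± 0.25) and C6 fell (log2 fold change -1.65 ± 0.21), beside a list median of -0.75, camera adjusted p = 9.24e-04, adjusted p = 0.250 with an estimated correlation. Of the 13 genes encoded by mitochondrial DNA, 8 fell and 5 did not pass (9 fell adjusted over the list alone). mt-Cytb, mt-Nd4 and mt-Atp6, of the respiratory chain and ATP synthase, fell (log2 fold changes -0.82 ± 0.093, -0.59 ± 0.085 and -0.52 ± 0.075), and the list as a whole had a median of -0.38, camera adjusted p = 4.76e-04, adjusted p = 0.400 with an estimated correlation. Among the 21 markers of pericentral hepatocytes, 9 rose, 3 fell (Cyp27a1, Cyp1a2, Slc1a4) and 9 did not pass (9 rose and 3 fell adjusted over the list alone). Lect2, Glul and Slc1a2, of cells around the central vein, rose (log2 fold changes 1.06 ± 0.089, 0.62 ± 0.074 and 1.04 ± 0.11), with a list median of 0.33, camera adjusted p = 2.35e-04, adjusted p = 0.183 with an estimated correlation. Of the 9 markers of B and plasma cells, 8 fell and 1 did not pass (8 fell adjusted over the list alone). Igkc and Ighm, immunoglobulin chains, fell (log2 fold changes -1.64 ± 0.25 and -2.16 ± 0.38), beside a list median of -0.82, camera adjusted p = 4.45e-04, adjusted p = 0.120 with an estimated correlation. Under total-count scaling 5 of these markers fell. From the 11 markers of erythroid cells and platelets, 8 fell and 3 did not pass (9 fell adjusted over the list alone). Slc4a1 and Alas2, a red cell anion exchanger and a haem enzyme, fell (log2 fold changes -1.96 ± 0.40 and -0.72 ± 0.15), and the list as a whole had a median of -1.07, camera adjusted p = 3.12e-04, adjusted p = 0.319 with an estimated correlation. Of the 18 markers of sinusoidal endothelial cells, which line liver capillaries, 3 rose (Bmp2, Wnt2, Oit3) and 15 did not pass (3 rose adjusted over the list alone). Bmp2 and Wnt2 rose (log2 fold changes 0.48 ± 0.10 and 0.69 ± 0.20), with a list median of 0.23, camera adjusted p = 0.0470, adjusted p = 0.890 with an estimated correlation. Without ketogenic replicate 2, 3 or 8 or chow replicate 15, 18 or 19 the list call was lost (adjusted p between 0.0527 and 0.152). Oit3 lost its call without ketogenic replicate 2, 3 or 8 or chow replicate 15, 18 or 19 (adjusted p between 0.0513 and 0.0730).

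The other 26 lists tested did not pass in this comparison (camera adjusted p between 0.132 and 0.932). These include the 36 genes of extracellular matrix and scarring, of which 7 rose, 4 fell (Col15a1, Tgfb2, Mmp2, Eln) and 25 did not pass (7 rose and 4 fell adjusted over the list alone). Of the 32 cytokine, chemokine and NF-kappaB target genes of inflammation, 7 rose, 2 fell (Ccl9, Il18) and 23 did not pass (7 rose and 2 fell adjusted over the list alone). Among the 28 genes of cholesterol synthesis and uptake, 4 rose (including Srebf2, Hsd17b7, Mylip), 10 fell and 14 did not pass (4 rose and 10 fell adjusted over the list alone). Of the 28 genes of glycolysis, fructose and glycogen metabolism, 7 rose, 11 fell and 10 did not pass (7 rose and 13 fell adjusted over the list alone). Under total-count scaling 7 of these and 2 extracellular matrix genes fell. Ldha rose (log2 fold change 1.06 ± 0.086) and Pygl fell (log2 fold change -0.71 ± 0.074), of lactate formation and glycogen breakdown. The lists of the unfolded protein response, the integrated stress response, lysosome and autophagy, bile acids, immediate early genes, nuclear oxidative phosphorylation genes, MHC class II, the urea cycle and the cell cycle did not pass either. Markers of hepatocytes as a whole, periportal hepatocytes, Kupffer cells, monocytes, neutrophils, T and NK cells, cholangiocytes, adipocytes, exocrine pancreas and sex-linked transcripts did not pass. A call was gained by lipoprotein assembly (main adjusted p = 0.161) without ketogenic replicate 4 (adjusted p = 0.0460), by the interferon response (main adjusted p = 0.176) without ketogenic replicate 4 or 6 or chow replicate 18 (adjusted p between 0.0351 and 0.0460) and by stellate cell markers (main adjusted p = 0.132) without ketogenic replicate 4 or chow replicate 16 (adjusted p between 0.0264 and 0.0460). With 1 member tested, the skeletal muscle list was not tested.

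**Figure D2:**
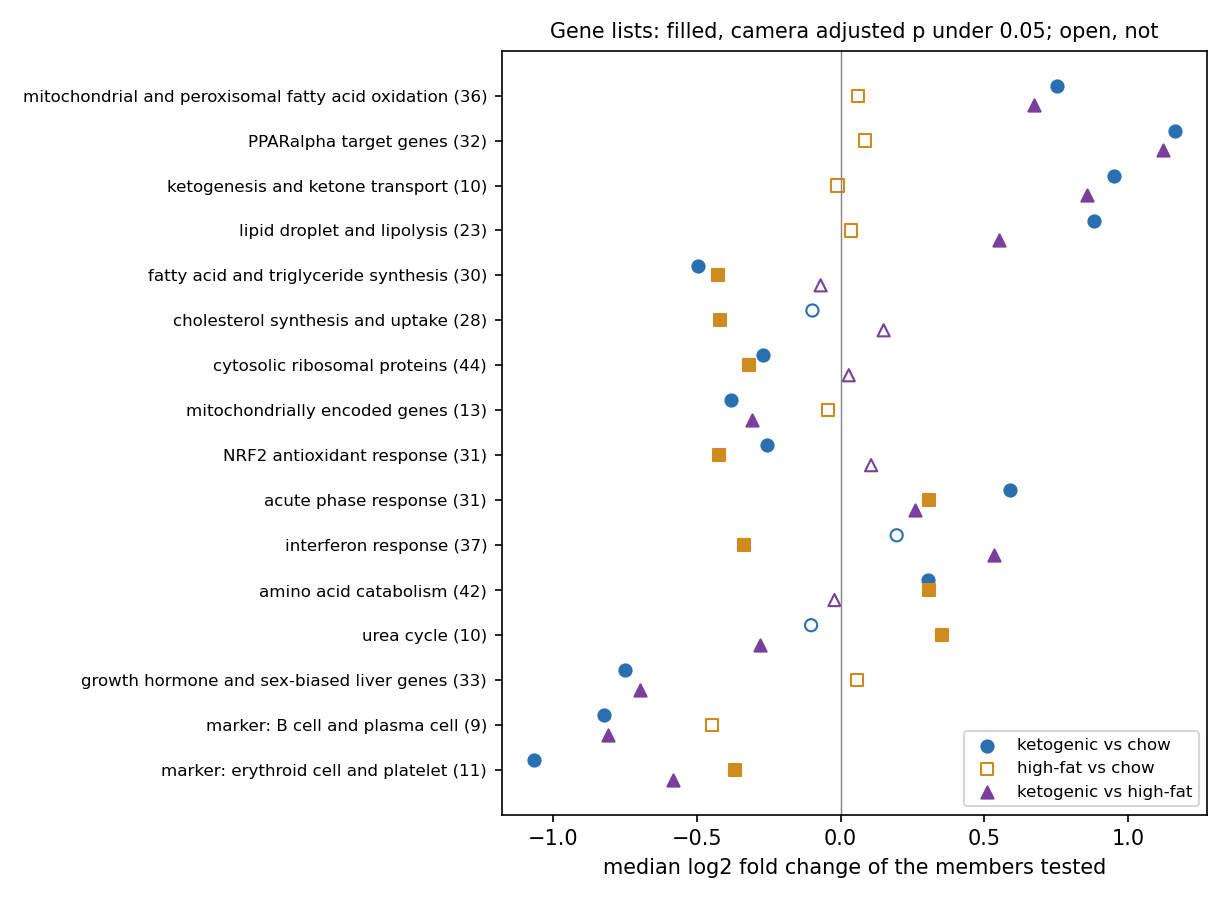
Median log2 fold change of 16 gene lists in the 3 comparisons (members tested in brackets), with 1 marker per list and comparison, filled where the camera adjusted p is under 0.05. The list of fatty acid oxidation has medians of 0.75 for ketogenic against chow, 0.062 for high-fat against chow and 0.67 for ketogenic against high-fat.

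The comparison of high-fat diet with chow measured what a fat-rich diet changed over the same 3 days. Of 30 genes for making fat 16 fell and 2 rose, of 31 antioxidant genes 15 fell, of 44 ribosomal protein genes 34 fell, and of 42 genes for breaking down amino acids 26 rose. With an estimated correlation the antioxidant list call held (adjusted p = 0.0432). Those of fat synthesis, ribosomal and amino acid genes were lost (0.506, 0.508 and 0.506) but kept by fry (0.0133, 0.0132 and 0.00427). Csad, which makes the precursor of taurine, fell 5.97-fold, from 488 ± 85.4 to 81.6 ± 16.1 normalised CPM (SD, n = 5 per diet; adjusted p = 6.09e-07). Nnmt, which methylates nicotinamide, had a log2 fold change of 1.81 ± 0.16 (SE), from 27.4 ± 6.40 to 96.1 ± 11.5 CPM (adjusted p = 1.69e-05). Cyp3a11, a drug-metabolising cytochrome P450 with close paralogs and so uncertain per gene, fell 5.46-fold, from 3401 ± 756 to 623 ± 179 (adjusted p = 0.0187), and Scd1 fell 2.84-fold, from 11987 ± 4402 to 4217 ± 1391 (adjusted p = 0.0153). In all, 1159 genes rose and 1023 fell, together 15.6% of those tested, of which 59 rose and 98 fell at least 2-fold. Without chow replicate 15, 681 genes fell, and with the effective-length offset 744 rose.

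Other large rises were in Scara5, a ferritin receptor (2.26 ± 0.51, adjusted p = 0.0113), and Cabyr, a calcium-binding protein first known from sperm (1.73 ± 0.32, adjusted p = 0.00310). Saa1, Cyp26b1, a retinoic acid hydroxylase, and Mfsd2a, a lipid transporter, rose by 2.42 ± 0.64, 2.21 ± 0.58 and 1.57 ± 0.44 (adjusted p = 0.0249, 0.0224 and 0.0321), with highest adjusted p over 20 alternatives of 0.0596, 0.0571 and 0.0810. Their calls were lost without chow replicate 15 or 16 for Saa1 (adjusted p = 0.0596 and 0.0539), without chow replicate 15 or high-fat replicate 12 for Cyp26b1 (0.0542 and 0.0571) and without chow replicate 16 or 18 or high-fat replicate 11, 12 or 14 for Mfsd2a (0.0565, 0.0602, 0.0595, 0.0669 and 0.0568). With only the 2 diets compared, Cyp26b1 and Mfsd2a also lost theirs (0.0510 and 0.0810). A further large fall was in Chrna4 (-3.46 ± 0.60, adjusted p = 0.00280, and -4.17 without high-fat replicate 9). Gstm3, a glutathione transferase, and Cyp2c69 and Cyp2c55, cytochrome P450 genes, have close paralogs and are uncertain per gene, with log2 fold changes of -2.46 ± 0.33, -2.40 ± 0.54 and -3.00 ± 0.81 (adjusted p = 5.30e-04, 0.01005 and 0.0260). Cyp2c55 lost its call without chow replicate 15 or high-fat replicate 10, 11, 12 or 14 (adjusted p = 0.0542, 0.0549, 0.0596, 0.0604 and 0.0595), and its adjusted p was between 4.77e-06 and 0.0604 over 20 alternatives.

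From the panel, Cpt1a rose by 0.80 ± 0.090 (adjusted p = 2.49e-05) and Pklr had a log2 fold change of -0.98 ± 0.16 (adjusted p = 0.00113). Pdk4, which restrains glucose oxidation, and Cyp7a1, the first enzyme of bile acid synthesis, had log2 fold changes of -1.33 ± 0.34 and -0.75 ± 0.19 (adjusted p = 0.0204 and 0.0197), calls lost without high-fat replicate 14 for Pdk4 (0.0518, between 0.00135 and 0.0518 over 20 alternatives) and without high-fat replicate 12 for Cyp7a1 (0.0530, between 2.87e-04 and 0.0530 over 20 alternatives). Fasn fell (log2 fold change -0.97 ± 0.29, adjusted p = 0.0379, between 0.0123 and 0.0879 over 20 alternatives). Its call was lost without high-fat replicate 10, 11, 12 or 14 (adjusted p = 0.0503, 0.0852, 0.0879 and 0.0720) or chow replicate 15 or 18 (0.0799 and 0.0605). With all libraries it was lost with limma-voom (0.0564), no low-count filter (0.0602), only the 2 diets compared (0.0759) and total-count scaling (0.0539). Fgf21, Cyp4a14, Angptl4, Srebf1, Pck1, G6pc, Igfbp1, Irs2, Ccl2, Adgre1 and Col1a1 did not pass, with log2 fold changes between -1.35 and 0.86. Pck1 passed without chow replicate 17 (adjusted p = 0.0403, between 0.0403 and 0.334 over 20 alternatives).

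Of the 44 ribosomal protein genes, 34 fell and 10 did not pass (43 fell adjusted over the list alone). Rpl37 fell (log2 fold change -0.35 ± 0.065), beside a list median of -0.32, camera adjusted p = 2.50e-21, adjusted p = 0.508 with an estimated correlation. Among the 31 NRF2 antioxidant genes, 15 fell and 16 did not pass (17 fell adjusted over the list alone). Gclc, Ephx1 and Me1, of glutathione, epoxides and NADPH, fell (log2 fold changes -0.76 ± 0.078, -1.03 ± 0.11 and -1.76 ± 0.17), and the list as a whole had a median of -0.42, camera adjusted p = 4.07e-20, adjusted p = 0.0432 with an estimated correlation. Of the 42 amino acid breakdown genes, 26 rose and 16 did not pass (29 rose and 2 fell adjusted over the list alone). Aass and Gldc, of lysine and glycine breakdown, rose (log2 fold changes 0.67 ± 0.076 and 0.65 ± 0.086), with a list median of 0.31, camera adjusted p = 3.86e-13, adjusted p = 0.506 with an estimated correlation. From the 10 urea cycle genes, 7 rose and 3 did not pass (8 rose adjusted over the list alone). Gls2, Asl and Oat, which supply or use its nitrogen, rose (log2 fold changes 0.43 ± 0.089, 0.48 ± 0.11 and 0.70 ± 0.16), beside a list median of 0.35, camera adjusted p = 7.77e-05, adjusted p = 0.506 with an estimated correlation. Of the 21 genes of methyl group metabolism, 6 rose and 15 did not pass (10 rose and 4 fell adjusted over the list alone). Ahcy and Bhmt, which handle homocysteine, rose (log2 fold changes 0.60 ± 0.098 and 1.15 ± 0.20), and the list as a whole had a median of 0.20, camera adjusted p = 4.02e-04, adjusted p = 0.508 with an estimated correlation.

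Of the 30 fat synthesis genes, 2 rose (Fads2, Nr1h3), 16 fell and 12 did not pass (3 rose and 17 fell adjusted over the list alone). Pnpla3, Pgd and G6pdx, a lipid droplet hydrolase and a pair of NADPH sources, fell (log2 fold changes -3.40 ± 0.31, -0.78 ± 0.11 and -2.06 ± 0.28), with a list median of -0.43, camera adjusted p = 1.00e-08, adjusted p = 0.506 with an estimated correlation. Among the 28 genes of cholesterol synthesis and uptake, 1 rose (Srebf2), 7 fell and 20 did not pass (2 rose and 9 fell adjusted over the list alone). Sc5d, Rdh11 and Pmvk, enzymes of or near the sterol pathway, fell (log2 fold changes -0.84 ± 0.12, -1.04 ± 0.18 and -0.999 ± 0.18), beside a list median of -0.42, camera adjusted p = 7.77e-05, adjusted p = 0.859 with an estimated correlation. Of the 28 genes of glycolysis, fructose and glycogen metabolism, 2 rose (Pdk2, Pfkfb2), 8 fell and 18 did not pass (2 rose and 10 fell adjusted over the list alone). Pdk2, which regulates pyruvate entry, rose (log2 fold change 0.36 ± 0.090) and Ppp1r3g fell (log2 fold change -3.50 ± 0.52), and the list as a whole had a median of -0.10, camera adjusted p = 0.0199, adjusted p = 0.859 with an estimated correlation. That list call was lost without high-fat replicate 14 or chow replicate 15 (adjusted p between 0.0581 and 0.0646). From the 19 clock genes, 8 rose and 11 did not pass (9 rose adjusted over the list alone). Tef, Per2 and Nr1d2 rose (log2 fold changes 0.53 ± 0.100, 0.82 ± 0.15 and 0.72 ± 0.15), with a list median of 0.31, camera adjusted p = 0.00257, adjusted p = 0.248 with an estimated correlation. Of the 19 heat shock genes, 4 rose (Hspb8, Hspa8, Dnaja1, Hsph1), 1 fell (Hspe1) and 14 did not pass (5 rose and 1 fell adjusted over the list alone). Hspb8 and Hspa8 rose (log2 fold changes 0.38 ± 0.057 and 0.79 ± 0.13), beside a list median of 0.20, camera adjusted p = 0.00568, adjusted p = 0.859 with an estimated correlation.

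Of the 37 interferon response genes, 12 fell and 25 did not pass (15 fell adjusted over the list alone). Bst2, Gbp6 and Isg15, antiviral effectors, fell (log2 fold changes -0.69 ± 0.11, -0.78 ± 0.14 and -0.80 ± 0.19), and the list as a whole had a median of -0.34, camera adjusted p = 4.42e-07, adjusted p = 0.551 with an estimated correlation. Among the 31 acute phase genes, 9 rose, 1 fell (Apcs) and 21 did not pass (11 rose and 1 fell adjusted over the list alone). Saa4, Steap4 and Orm3 rose (log2 fold changes 1.30 ± 0.14, 0.71 ± 0.12 and 1.85 ± 0.35), with a list median of 0.31, camera adjusted p = 3.36e-05, adjusted p = 0.508 with an estimated correlation. Markers of Kupffer cells fell as a list (median -0.25, camera adjusted p = 0.0148, adjusted p = 0.972 with an estimated correlation), while 1 of its 16 members passed on its own (Cd207; 0 adjusted over the list alone). That list call was lost without high-fat replicate 9, 11 or 12 or chow replicate 19 (adjusted p between 0.0572 and 0.0727). Cd207 lost its call without high-fat replicate 9, 12 or 14 or chow replicate 15, 16 or 18 (adjusted p between 0.0510 and 0.103). Markers of erythroid cells and platelets also fell as a list (median -0.37, camera adjusted p = 0.0295, adjusted p = 0.859 with an estimated correlation), with none of its 11 members past the threshold, over all genes or adjusted over the list alone. Without high-fat replicate 9, 10 or 14 or chow replicate 17, 18 or 19 that call was lost (adjusted p between 0.0581 and 0.0784).

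The other 34 lists did not pass (camera adjusted p between 0.0569 and 0.998). Of the 36 fatty acid oxidation genes, 5 rose (Cpt1a, Acad10, Acot12, Echs1, Etfdh), 5 fell (Abcd3, Acot1, Ehhadh, Crot, Abcd2) and 26 did not pass (6 rose and 5 fell adjusted over the list alone). Among the 10 genes of ketone bodies, 2 rose (Ppara, Acat1), 2 fell (Acss2, Slc16a1) and 6 did not pass (2 rose and 2 fell adjusted over the list alone). From the 32 PPARalpha targets, 4 rose (Cpt1a, Fabp2, Gpt2, Creb3l3), 5 fell (Pltp, Pdk4, Fabp1, Acot1, Ehhadh) and 23 did not pass (4 rose and 5 fell adjusted over the list alone). Of the 23 genes of lipid droplets, 3 rose (Fabp2, Fitm2, Plin4), 2 fell (Pnpla3, Lpl) and 18 did not pass (3 rose and 4 fell adjusted over the list alone). Rises and falls under total-count scaling were 4 and 1 for oxidation, 4 and 3 for PPARalpha targets and 1 and 2 for lipid droplets (3 and 5 with the effective-length offset). Of the 36 genes of extracellular matrix and scarring, 2 rose (including Fn1), 4 fell (Col15a1, Tagln, Lum, Mmp14) and 30 did not pass (2 rose and 4 fell adjusted over the list alone). Among the 32 inflammation genes, 2 fell (Ccl9, Nlrp3) and 30 did not pass (2 fell adjusted over the list alone). Fabp2 rose (log2 fold change 0.70 ± 0.095) and Abcd3 fell (log2 fold change -0.47 ± 0.088), a fatty acid carrier and a peroxisomal transporter. Insulin signalling, glucose synthesis, lipoproteins, bile acids, lysosome and autophagy, both stress responses, xenobiotic metabolism, growth hormone and sex-biased genes, oxidative phosphorylation, the tricarboxylic acid cycle, mitochondrially encoded genes, MHC class II, the cell cycle and immediate early genes did not pass. Nor did the markers of hepatocytes as a whole, of periportal and pericentral hepatocytes, or of endothelial, stellate, B, T and NK cells, monocytes, neutrophils, cholangiocytes, adipocytes, exocrine pancreas and sex-linked transcripts. Calls were gained by extracellular matrix (main adjusted p = 0.112) without high-fat replicate 14 or chow replicate 15 (adjusted p between 0.0164 and 0.0329), by oxidative phosphorylation (main adjusted p = 0.112) without high-fat replicate 9 or 10 or chow replicate 18 (adjusted p between 0.00621 and 0.0327), by B and plasma cell markers (main adjusted p = 0.0569) without high-fat replicate 10, 12 or 14 or chow replicate 15 or 19 (adjusted p between 0.00751 and 0.0467) and by endothelial markers (main adjusted p = 0.239) without chow replicate 16 (adjusted p = 0.0169). Acot12 lost its call without high-fat replicate 12 (adjusted p = 0.0611). Acat1 lost its call without high-fat replicate 11 or 12 or chow replicate 16 or 18 (adjusted p between 0.0573 and 0.0715). Fitm2 lost its call without high-fat replicate 11, 12 or 14 or chow replicate 16, 17, 18 or 19 (adjusted p between 0.0563 and 0.0890). Fn1 lost its call without high-fat replicate 10, 11, 12 or 14 or chow replicate 15, 16, 17 or 19 (adjusted p between 0.0618 and 0.102). Tagln lost its call without high-fat replicate 12 or 14 or chow replicate 15 or 18 (adjusted p between 0.0517 and 0.0646). Lum lost its call without high-fat replicate 10, 11 or 12 or chow replicate 15 (adjusted p between 0.0524 and 0.0666). Nlrp3 lost its call without high-fat replicate 11 or 12 or chow replicate 15 or 16 (adjusted p between 0.0512 and 0.0669).

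The comparison of ketogenic with high-fat diet tested if their responses differed. In it, rose and fell mean higher and lower on the ketogenic diet, whichever diet moved from chow. On the ketogenic diet 35 of 36 genes of fatty acid oxidation, 9 of 10 of ketone bodies and 15 of 23 of lipid droplets were higher. Fgf21 was higher 7.15-fold, from 1.11 ± 0.805 to 7.85 ± 4.22 CPM (SD, n = 5 per diet; adjusted p = 0.00228). Cidec was higher 10.3-fold, from 3.40 ± 1.91 to 35.4 ± 9.47 (adjusted p = 3.49e-05), and Cpt1a 1.99-fold, from 314 ± 42.3 to 626 ± 52.9 (adjusted p = 5.41e-07). Scd1 was lower 35.0-fold, from 4217 ± 1391 to 121 ± 55.9 (adjusted p = 4.04e-06). Of the genes tested, 1826 were higher and 1818 lower on the ketogenic diet, together 26.1%, of which 213 were higher and 185 lower at least 2-fold. With scaling by total count only, chosen after seeing the data, higher genes made up 70.6% of the calls against 50.1%, and 960 were lower.

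Apoa4 rose by 3.56 ± 0.37 (SE; adjusted p = 2.64e-05) and Rad51b, a DNA repair gene, by 3.23 ± 0.25 (adjusted p = 1.46e-07). Cyp2b9, Cyp2a22 and Acot3, a peroxisomal thioesterase, rose by 5.92 ± 0.78, 4.55 ± 0.36 and 3.60 ± 0.43 (adjusted p = 1.89e-04, 1.85e-06 and 8.12e-05), and Cyp2b9 by 6.54 without high-fat replicate 14. Close paralogs make the values of these 3 genes uncertain. Falls beside Scd1 were in Cabyr (-3.66 ± 0.36, adjusted p = 1.14e-05) and Serpina9, a protease inhibitor of B cells (-3.52 ± 0.62, adjusted p = 0.00135). Mup7, Mup2 and Mup17, uncertain per gene, had log2 fold changes of -3.93 ± 0.58, -3.86 ± 0.64 and -3.20 ± 0.61, and Mup2 of -4.61 without ketogenic replicate 6. Summed over 22 genes, a sum that read sharing within the family does not change, the Mup family stood at 44994 ± 10496 CPM on the ketogenic diet, 115127 ± 39328 on the high-fat diet and 104100 ± 27593 on chow.

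Panel genes Cyp4a14 and Pdk4 were higher by 2.15 ± 0.39 and 1.59 ± 0.34 (adjusted p = 0.00160 and 0.00475). Igfbp1, an IGF carrier repressed by insulin, rose by 2.28 ± 0.70 (adjusted p = 0.0311, between 0.00476 and 0.0924 over 20 alternatives). That call was lost without high-fat replicate 9, 10 or 14 (adjusted p = 0.0568, 0.0677 and 0.0684) or ketogenic replicate 4 (0.0924, with a rise of 1.58). Srebf1 fell (log2 fold change -0.70 ± 0.18, adjusted p = 0.0129, between 4.38e-04 and 0.0617 over 20 alternatives), a call lost with the effective-length offset (0.0617). Pklr fell (log2 fold change -0.50 ± 0.16, adjusted p = 0.0301, between 0.00730 and 0.0797 over 20 alternatives), a call lost without ketogenic replicate 2, 3 or 6 (0.0593, 0.0701 and 0.0593) or high-fat replicate 9, 11 or 14 (0.0558, 0.0797 and 0.0686), and with no low-count filter (0.0647) or total-count scaling (0.0566). Angptl4 (0.79 ± 0.29, adjusted p = 0.0626) and Fasn (-0.75 ± 0.29, adjusted p = 0.0746) did not pass, nor did Pck1, G6pc, Irs2, Cyp7a1, Saa1, Ccl2, Adgre1 and Col1a1 (log2 fold changes between -0.68 and 0.88). Calls were gained by Angptl4 with DESeq2 (adjusted p = 0.0247), only the 2 diets compared (0.0142) and total-count scaling (0.0496) and without high-fat replicate 12 (0.0467, between 0.0142 and 0.131 over 20 alternatives), and by Saa1 without ketogenic replicate 4 (0.0329, between 0.0329 and 0.806 over 20 alternatives), where its log2 fold change was -1.58 against -0.68 ± 0.60. Fasn passed with the effective-length offset (adjusted p = 0.0215) and with only the 2 diets compared (0.00771), between 0.00771 and 0.154 over 20 alternatives, and Cyp7a1 with DESeq2 (0.0333), between 0.0333 and 0.197 over 20 alternatives.

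Of the 36 fatty acid oxidation genes, 35 rose and 1 did not pass (36 rose adjusted over the list alone). Acadm, Acadl and Pex11a, dehydrogenases and a factor of peroxisome division, rose (log2 fold changes 1.12 ± 0.075, 0.89 ± 0.061 and 1.57 ± 0.11), beside a list median of 0.67, camera adjusted p = 4.31e-56, adjusted p = 0.00996 with an estimated correlation. Among the 32 PPARalpha targets, 26 rose, 1 fell (Pltp) and 5 did not pass (27 rose and 1 fell adjusted over the list alone). Aldh3a2 and Slc22a5, a fatty aldehyde enzyme and a carnitine carrier, rose (log2 fold changes 1.37 ± 0.11 and 1.39 ± 0.11), and the list as a whole had a median of 1.12, camera adjusted p = 1.27e-32, adjusted p = 0.0102 with an estimated correlation. Of the 10 genes of ketone bodies, 9 rose and 1 did not pass (9 rose and 1 fell adjusted over the list alone). Bdh1 and Slc16a7, which form and move them, rose (log2 fold changes 1.47 ± 0.087 and 1.43 ± 0.089), with a list median of 0.86, camera adjusted p = 6.54e-21, adjusted p = 7.08e-04 with an estimated correlation. From the 23 genes of lipid droplets and lipolysis, 15 rose, 1 fell (Pnpla3) and 7 did not pass (16 rose and 2 fell adjusted over the list alone). Hsd17b11, Plin5 and Mgll rose (log2 fold changes 0.85 ± 0.072, 1.15 ± 0.097 and 1.07 ± 0.10), beside a list median of 0.55, camera adjusted p = 2.25e-14, adjusted p = 0.00477 with an estimated correlation. Of the 23 genes of the tricarboxylic acid cycle, 13 rose and 10 did not pass (14 rose adjusted over the list alone). Idh2 and Suclg1 rose (log2 fold changes 0.90 ± 0.092 and 0.54 ± 0.068), and the list as a whole had a median of 0.25, camera adjusted p = 1.98e-07, adjusted p = 0.393 with an estimated correlation. Among the 20 genes of glucose synthesis, 7 rose, 1 fell (Got1) and 12 did not pass (8 rose and 1 fell adjusted over the list alone). Gk, Pcx and Gpd1 rose (log2 fold changes 1.27 ± 0.083, 0.52 ± 0.095 and 0.42 ± 0.085), with a list median of 0.27, camera adjusted p = 0.00165, adjusted p = 0.393 with an estimated correlation.

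Of the 37 interferon response genes, 24 rose and 13 did not pass (26 rose adjusted over the list alone). Usp18, Irf7 and Zbp1, regulators and a nucleic acid sensor, rose (log2 fold changes 1.62 ± 0.18, 0.83 ± 0.099 and 1.30 ± 0.23), beside a list median of 0.53, camera adjusted p = 2.00e-09, adjusted p = 0.383 with an estimated correlation. Of the 16 markers of Kupffer cells, the resident liver macrophages, 5 rose (Fcna, Vsig4, Cd163, C1qb, Cd5l) and 11 did not pass (6 rose adjusted over the list alone). Fcna, a ficolin, rose (log2 fold change 0.51 ± 0.12), and the list as a whole had a median of 0.37, camera adjusted p = 0.00406, adjusted p = 0.648 with an estimated correlation. Among the 31 acute phase genes, 10 rose, 1 fell (Serpina3k) and 20 did not pass (11 rose and 2 fell adjusted over the list alone). Itih4 and Cp, plasma proteins, rose (log2 fold changes 0.47 ± 0.093 and 0.33 ± 0.069), with a list median of 0.26, camera adjusted p = 0.0332, adjusted p = 0.665 with an estimated correlation. Without ketogenic replicate 4 or 6 or high-fat replicate 12 or 14 the list call was lost (adjusted p between 0.0635 and 0.235). Of the 36 genes of extracellular matrix and scarring, 6 rose and 30 did not pass (5 rose adjusted over the list alone). Mmp14, Lum and Dcn, a matrix protease and small proteoglycans, rose (log2 fold changes 0.71 ± 0.090, 1.03 ± 0.13 and 0.39 ± 0.091), beside a list median of 0.12, camera adjusted p = 0.0493, adjusted p = 0.7096 with an estimated correlation. Leaving out ketogenic replicate 2 or 8 or high-fat replicate 10 or 12 ended the list call (adjusted p between 0.0510 and 0.177). From the 19 markers of stellate cells and fibroblasts, the matrix-forming cells, 5 rose (Bmp10, Dcn, Hgf, Cygb, Bmp5) and 14 did not pass (5 rose adjusted over the list alone). Bmp10, Hgf and Cygb rose (log2 fold changes 0.79 ± 0.14, 0.80 ± 0.19 and 0.43 ± 0.11), and the list as a whole had a median of 0.19, camera adjusted p = 0.0332, adjusted p = 0.644 with an estimated correlation. That list call was lost without ketogenic replicate 2 or high-fat replicate 10 (adjusted p between 0.0697 and 0.0882). Of the 33 genes that handle foreign compounds, 19 rose, 1 fell (Cyp2c29) and 13 did not pass (21 rose and 1 fell adjusted over the list alone). Ugt1a1 and Cyp2e1 rose (log2 fold changes 0.79 ± 0.087 and 0.64 ± 0.089), with a list median of 0.64, camera adjusted p = 6.17e-08, adjusted p = 0.308 with an estimated correlation. Vsig4 lost its call without high-fat replicate 11 (adjusted p = 0.0520). Cd163 lost its call without ketogenic replicate 3 or 4 or high-fat replicate 11 (adjusted p between 0.0524 and 0.0547). C1qb lost its call without ketogenic replicate 2 or 4 or high-fat replicate 11 (adjusted p between 0.0531 and 0.0567).

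Of the 10 urea cycle genes, 2 rose (Slc25a13, Oat), 7 fell and 1 did not pass (2 rose and 7 fell adjusted over the list alone). Ass1 and Cps1, which form argininosuccinate and carbamoyl phosphate, fell (log2 fold changes -1.09 ± 0.14 and -0.76 ± 0.14), beside a list median of -0.28, camera adjusted p = 0.00160, adjusted p = 0.425 with an estimated correlation. Among the 18 markers of periportal hepatocytes, around the portal vein, 3 rose (Apoa4, Hsd17b13, Ctsc), 9 fell and 6 did not pass (3 rose and 9 fell adjusted over the list alone). Gls2 and Etnppl fell (log2 fold changes -1.07 ± 0.090 and -1.23 ± 0.18), and the list as a whole had a median of -0.28, camera adjusted p = 0.0137, adjusted p = 0.607 with an estimated correlation. Of the 21 markers of pericentral hepatocytes, 9 rose, 2 fell (Cyp27a1, Gulo) and 10 did not pass (9 rose and 2 fell adjusted over the list alone). Lect2 and Glul rose (log2 fold changes 0.77 ± 0.089 and 0.47 ± 0.074), with a list median of 0.19, camera adjusted p = 0.00181, adjusted p = 0.368 with an estimated correlation. From the 13 mitochondrially encoded genes, 2 rose (mt-Nd2, mt-Nd1), 8 fell and 3 did not pass (2 rose and 9 fell adjusted over the list alone). mt-Cytb and mt-Nd4 fell (log2 fold changes -0.92 ± 0.093 and -0.61 ± 0.085), beside a list median of -0.31, camera adjusted p = 3.58e-04, adjusted p = 0.430 with an estimated correlation. Of the 42 nuclear genes of oxidative phosphorylation, 7 rose and 35 did not pass (6 rose adjusted over the list alone). Ndufs1 and Uqcrc2, of respiratory complexes, rose (log2 fold changes 0.31 ± 0.057 and 0.37 ± 0.071), and the list as a whole had a median of 0.099, camera adjusted p = 0.0195, adjusted p = 0.803 with an estimated correlation. That list call was lost without ketogenic replicate 8 or high-fat replicate 12 or 14 (adjusted p between 0.0943 and 0.134). Under total-count scaling 19 of the 42 rose. Among the 34 genes of lysosome and autophagy, 11 rose, 3 fell (Wipi1, Tfe3, Glb1) and 20 did not pass (12 rose and 4 fell adjusted over the list alone). Lipa, Hexa and Bnip3, acid hydrolases and a mitophagy receptor, rose (log2 fold changes 0.64 ± 0.085, 0.57 ± 0.084 and 0.62 ± 0.092), with a list median of 0.12, camera adjusted p = 0.0195, adjusted p = 0.607 with an estimated correlation.

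Of the 33 growth hormone and sex-biased genes, 6 rose, 15 fell and 12 did not pass (6 rose and 18 fell adjusted over the list alone). C6, a complement component, fell (log2 fold change -1.83 ± 0.21), beside a list median of -0.70, camera adjusted p = 6.95e-05, adjusted p = 0.192 with an estimated correlation. Of the 9 markers of B and plasma cells, 4 fell (including Jchain, Igkc, Ms4a1) and 5 did not pass (4 fell adjusted over the list alone). Jchain and Igkc fell (log2 fold changes -0.97 ± 0.25 and -0.93 ± 0.26), and the list as a whole had a median of -0.81, camera adjusted p = 0.0362, adjusted p = 0.383 with an estimated correlation. That list call was lost without ketogenic replicate 2 or high-fat replicate 12 or 14 (adjusted p between 0.0510 and 0.0583). Among the 11 markers of erythroid cells and platelets, 2 fell (Slc4a1, Alas2) and 9 did not pass (2 fell adjusted over the list alone). Alas2 fell (log2 fold change -0.60 ± 0.15), with a list median of -0.58, camera adjusted p = 0.0467, adjusted p = 0.648 with an estimated correlation. Without ketogenic replicate 2, 4 or 6 or high-fat replicate 9, 11 or 12 the list call was lost (adjusted p between 0.0502 and 0.131). Ms4a1 lost its call without ketogenic replicate 2, 4, 6 or 8 or high-fat replicate 10, 11, 12 or 14 (adjusted p between 0.0532 and 0.0842).

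The other 27 lists did not pass (camera adjusted p between 0.0745 and 0.950). Of the 30 fat synthesis genes, 5 rose (Mogat1, Acsl1, Elovl5, Fads2, Lpin2), 6 fell and 19 did not pass (5 rose and 6 fell adjusted over the list alone). Mogat1 and Acsl1 rose (log2 fold changes 1.23 ± 0.22 and 0.49 ± 0.091) and Mlxipl fell (log2 fold change -0.87 ± 0.11), of triglyceride assembly, fatty acid activation and glucose sensing. Among the 31 NRF2 antioxidant genes, 10 rose, 1 fell (Gstp1) and 20 did not pass (10 rose and 2 fell adjusted over the list alone). Of the 42 amino acid breakdown genes, 10 rose, 12 fell and 20 did not pass (15 rose and 13 fell adjusted over the list alone). From the 44 ribosomal protein genes, 1 rose (Rpl3) and 43 did not pass (0 rose adjusted over the list alone). Under total-count scaling 8 of the ribosomal genes rose, and 15 amino acid breakdown genes rose and 10 fell. Of the 32 inflammation genes, 8 rose, 1 fell (Cxcl9) and 23 did not pass (8 rose and 1 fell adjusted over the list alone). Cholesterol, glycolysis, insulin signalling, bile acid, lipoprotein, both stress response, methyl group, clock, cell cycle, immediate early, heat shock and MHC class II lists did not pass, nor did markers of hepatocytes as a whole, endothelial cells, monocytes, neutrophils, T and NK cells, cholangiocytes, adipocytes, exocrine pancreas and sex-linked transcripts. Calls were gained by cholesterol synthesis (main adjusted p = 0.0745) without ketogenic replicate 3 or 4 or high-fat replicate 9 or 10 (adjusted p between 0.00186 and 0.0436), by insulin signalling (main adjusted p = 0.0903) without high-fat replicate 11 (adjusted p = 0.0371), by lipoprotein assembly (main adjusted p = 0.0750) without ketogenic replicate 4 (adjusted p = 0.0245) and by inflammation genes (main adjusted p = 0.0750) without ketogenic replicate 8 or high-fat replicate 14 (adjusted p between 0.0224 and 0.0392). They were also gained by immediate early genes (main adjusted p = 0.117) without ketogenic replicate 3 or high-fat replicate 11 (adjusted p between 0.0287 and 0.0411), by heat shock (main adjusted p = 0.101) without ketogenic replicate 6 (adjusted p = 0.0128) and by endothelial markers (main adjusted p = 0.280) without high-fat replicate 14 (adjusted p = 0.0144). Rpl3 lost its call without ketogenic replicate 2, 3, 4, 6 or 8 or high-fat replicate 11, 12 or 14 (adjusted p between 0.0531 and 0.126).

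A list's median, mean and test direction differed in sign only among lists that did not pass. This was so in the ketogenic comparison with chow for MHC class II, extracellular matrix, the unfolded protein response, the urea cycle and the markers of periportal hepatocytes, neutrophils and sex-linked transcripts. In the high-fat comparison with chow it was so for fatty acid oxidation, PPARalpha targets, insulin signalling, bile acids, lipoproteins, lipid droplets, MHC class II, the tricarboxylic acid cycle, xenobiotic metabolism, immediate early genes, mitochondrially encoded genes and the markers of adipocytes and sex-linked transcripts. Between the ketogenic and high-fat diets it was so for the unfolded protein response, methyl group metabolism, the clock and hepatocyte markers. With an estimated correlation, list calls held for fatty acid oxidation, PPARalpha targets, ketone bodies and lipid droplets in both comparisons of the ketogenic diet, and for the NRF2 antioxidant genes alone in the high-fat comparison with chow.

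Responses to the ketogenic and the high-fat diet were compared across genes, which are not independent replicates, and both comparisons used the same chow libraries. Across 13967 genes the log2 fold changes had a Pearson r of 0.492 and a Spearman rho of 0.437, while 20 simulations of unchanged diets against shared chow libraries gave a median r of 0.498 (0.469 to 0.541). The covariance was 0.0828 against a simulated 0.0186, a difference of 0.0642. With the chow libraries split 2 against 3 between the comparisons, the median r was 0.322 (0.228 to 0.383) and the median covariance 0.0632. Both diets raised 644 genes, where independent lists would share 187, and lowered 586, where they would share 149. The simulations called at most 1 gene on either diet and shared 0, so they give no reference for this overlap. In the split, a median of 272 genes rose and 256 fell in both, where independent lists would share 65.8 and 53.8. In 64 genes the calls went in opposite directions. Csad, Scd1, Chrna4, Pnpla3, Me1 and Pklr were among those that fell on both diets, and Cpt1a, Fabp2, Saa4 and Cyp17a1 among those that rose on both.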

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

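Total-count scaling, tests of short transcripts, Mup paralogs and female livers, and the division of sex-biased genes by direction were chosen after results were seen. A library far from the other 4 of its diet was sought with Dixon's test, on the log2 CPM scale for genes, in 162 groups, of which 8.1 would stand apart by chance and 10 did. On the high-fat diet these were Scara5 in replicate 11 (31.6 CPM, others 15.2 to 18.4) and Cabyr in replicate 14 (16.9, others 9.24 to 10.3). On chow they were Col1a1 in replicate 18 (4.65, others 1.73 to 2.19), Pdk4 in replicate 18 (33.5, others 13.8 to 17.5), Apoa4 in replicate 15 (215, others 109 to 127) and Acot3 in replicate 19, which was low (6.21, others 13.5 to 18.3). On the ketogenic diet they were Igfbp1 in replicate 4 (167, others 33.0 to 52.6), Gstm3 in replicate 8 (14.3, others 3.83 to 5.19), the share of reads from Alb in replicate 8, which was low (6.49%, others 6.99 to 7.08%), and the third principal component in replicate 8 (6.63, others -1.44 to -0.81).

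A pair of genes drew attention for moving in opposite directions on the diets against chow, a difference tested directly between the ketogenic and high-fat diets. Cabyr had log2 fold changes of -1.93 on the ketogenic diet (adjusted p = 0.00148) and 1.73 on the high-fat diet (adjusted p = 0.00310), which differed by -3.66 (adjusted p = 1.14e-05). Rad51b had log2 fold changes of 1.03 on the ketogenic diet (adjusted p = 0.00108) and -2.20 on the high-fat diet (adjusted p = 3.83e-05), which differed by 3.23 (adjusted p = 1.46e-07).

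Genes differed in large numbers between diets. With an offset for GC content, 3889 of the 4296 calls for ketogenic against chow were shared (correlation of fold changes 0.996), and with one for effective length 3423 (0.971), so neither trend was the whole cause there. In that order the shared calls were 2159 and 1432 of 2182 for high-fat against chow (0.9996 and 0.949) and 3324 and 2739 of 3644 for ketogenic against high-fat (0.996 and 0.967), and how much effective length adds to the former is left open. Of 100 divisions of the 10 libraries compared, drawn from 126, 1 gave as many calls as the real one in each comparison, namely the real one itself: 4296 against a next highest of 1 for ketogenic against chow, 2182 against 330 for high-fat against chow, and 3644 against 103 for ketogenic against high-fat. An unrecorded batch that followed the diets cannot be told apart from the diets, and a response to diet is consistent with these values.

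Ribosomal protein genes fell against chow, with medians of -0.271 (ketogenic) and -0.318 (high-fat). These calls were lost with an estimated correlation (adjusted p = 0.558 and 0.508), not with fry (0.00979 and 0.0132). With the GC offset the medians were -0.277 and -0.323, so a GC trend does not explain the fall. Loss of short transcripts would also lower nuclear oxidative phosphorylation genes, which have a median effective length of 652 against 484 for ribosomal protein genes and 2550 for all genes, but their medians were 0.0076 (SE 0.035) and -0.0725 (SE 0.022). These SE are over genes, not mice, and the genes vary together (estimated correlation 0.669 and 0.666). How much such a loss adds is left open. The result may reflect lower ribosomal protein transcript levels, and no biological cause was tested.

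On the ketogenic diet, 15 of 18 male-biased genes fell and 6 of 7 female-biased genes rose, against 0 and 1 on the high-fat diet. Between the ketogenic and high-fat diets directly, 14 of 18 were lower and 6 of 7 higher, and the call of the list as a whole was lost with an estimated correlation (adjusted p = 0.250 against chow and 0.192 against high-fat). Reads shared between Mup paralogs do not account for this, since 10 of 12 male-biased genes outside that family fell, with a median of -1.263. Female livers among the ketogenic libraries do not account for it either, since the lowest of these had Y-linked transcripts at 101.6% of the chow mean. Lower growth hormone signalling could contribute, but Igf1, Igfals, Socs2 and Cish had a median of -0.540 and 0 of 4 passed, so that it cannot be told.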

How the results depend on the processing

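No paired analysis was possible because no replicate number recurs between diets. No value past the threshold reversed under any alternative, while some that did not pass changed sign, such as Fgf21 for high-fat against chow (-0.28 to 0.49). Of the counts of called genes, those that differed by over 1.5 times were, for ketogenic against chow, 1265 lower under total-count scaling (main 2038), chosen after seeing the data. For high-fat against chow they were 744 higher with the effective-length offset (main 1159) and 681 lower without chow replicate 15 (main 1023, and 681 to 1313 over the libraries left out). For ketogenic against high-fat, 960 were lower under total-count scaling (main 1818). The cause was not tested. Leaving out 1 library gave 1950 to 2178 higher and 1652 to 1896 lower genes for ketogenic against chow, 802 to 1441 higher for high-fat against chow, and 1479 to 1982 higher and 1381 to 1961 lower for ketogenic against high-fat. For ketogenic against chow, high-fat against chow and ketogenic against high-fat, the main test passed 22, 14 and 21 lists. Camera with an estimated correlation passed 4, 1 and 4, and fry 24, 10 and 20. Fry ended 11 of the main list calls and added 8. Without 1 library the lists numbered 19 to 24, 13 to 15 and 16 to 23. The correlation of the diets' responses was 0.322 with the chow libraries split (main 0.492), where no chow library is shared and each comparison has fewer of them, and 0.468 to 0.532 without 1 library. Of 87 values for genes named for size or from the panel, 17 changed their side of the threshold under some alternative. Over all alternatives, values of named genes and list members kept their side in 11632 cases, lost it in 331 and gained it in 118, of which leaving out 1 library made 234 and 52. Genes that the filter of an alternative removed gave no value there, and those to which DESeq2 gave no adjusted p were counted as keeping their side. Depth limited genes of few reads, such as Il6, Tnf and Timp1 with 0 to 9 reads per library, which were not tested.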

Other observations

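After the libraries were compared, replicates of a diet fell, in number order, into sets by share of Mup reads. On the high-fat diet this was 13.4, 14.4 and 12.2% in replicates 9, 10 and 11, and 8.01 and 7.71% in replicates 12 and 14. The chi-square per degree of freedom was 18.48 to 40.51 among the former, 23.6 between the latter and 71.68 to 96.86 across. On the ketogenic diet the Mup share was 3.84 to 4.16% in replicates 2, 3 and 4, 6.03% in 6 and 5.06% in 8. This chi-square was 20.32 to 33.96 among the first 3, 53.72 between the other 2 and 54.56 to 74.78 across. On chow, replicate 19 had 14.5% and the others 8.4 to 10.65%, and its chi-square against them was 54.94 to 110.47. Mup reads enter this chi-square, so it is not a separate test of the sets. No cause was tested, nor whether a diet's 5 libraries are independent, as all p values assume.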
